A study of Oryza sativa Japonica Group with 6 samples.

How the data were processed

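Endosperm samples of rice were compared between 2 temperature groups of 3 samples each, grouped by the treatment label. Per the labels' protocols, total RNA was depleted of ribosomal RNA, fragmented, made into cDNA libraries and sequenced in pairs on an Illumina HiSeq instrument. The submitters' processing notes name cutadapt 1.10, FastQC 0.10.1, HISAT2 2.0.4 and StringTie 1.3.0 without saying which step each was used for. The genome build, the annotation and the use of strand in quantification are not given in the sources used here.

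Expression values were deposited by the authors as FPKM (fragments normalized to transcript length and library total), per the file headers, rounded to 2 decimals, with 1 column per sample. The score used from the authors' deposited starch-metabolism table is a Pearson correlation of an mRNA with an lncRNA, per the file headers, and which values entered it is not given in the sources used here. Recomputed on the FPKM of the 6 samples, it came within 0.001 of the deposited value in 91 of 130 pairs with an unambiguous lncRNA row. The largest absolute difference was 0.0436. Further deposited tables gave the position, length and class code of each lncRNA, the lncRNAs the authors called changed, and microRNA pairings, of which 3 lines were empty and not used here. The authors' test and thresholds for changed lncRNAs are not given in the sources used here.

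Read counts could not be recovered from the values. Low values lay near whole multiples of a gene's lowest value in as few as 20.2% of cases (tolerance 0.1), so depth is unknown, and no count model, interval or detection limit was computed. FPKM sums per sample ranged from 365035 to 380742, and 5300 to 5892 of 30485 rows were listed at 0. A value of 0 can be a failed estimate: GLB1, an abundant storage globulin, was listed at 0 in 4 of 6 samples.

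Tests were run in R 4.3.3 with limma 3.58.1 on log2(FPKM + 1), with the prior variance a trend on the mean, two-sided, without a replicate block, and with Benjamini-Hochberg adjustment at 0.05. Rows with a mean over the 6 samples of at least 0.5 FPKM were tested, mRNA genes and lncRNAs apart. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and means ± SD are of FPKM. An adjusted p is from limma unless camera or Fisher's exact test is named. Of the lncRNA rows, 578 covered 532 loci, and rows of a locus that occurs more than once were matched to the authors' calls only where the authors' deposited table lists as many rows of it, as for MSTRG.15514.

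Of 11 gene lists, 10 were fixed before the data were examined and 1 is the set of mRNAs in the authors' deposited starch-metabolism table, chosen by the study on these samples. They were tested with limma's camera at a preset correlation of 0.01, adjusted over all lists, with an estimated correlation as an alternative. A list needed 5 tested members. The sources used here do not pair the LOC identifiers with names. The pairing of a symbol with its identifier was written by hand from rice nomenclature for the list members, 10 of the identifiers after the table had been opened but before any fold change was seen. Of 126 list genes, 17 were not matched to a row. The reference gene table (assembly ASM3414082v1) holds no such identifiers; 65 symbols were found in it once, all 65 on the chromosome given by the identifier, and 243 of 250 pairs on 1 chromosome were in the same order. The other pairs involve GLUC and GLB1, symbols that the reference gives to other genes, so the identity of these genes was not checked by it. Neither passed the test on the deposited scale. Symbols not found once in the reference, among them GLUB1, GLUD, GBSSI, BEIIb, BT1 and RAB16A, were not checked by it either. Lists by product name were not built, as no product names were at hand.

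Named genes followed a rule fixed before the data were examined. It took the 10 largest rises and falls past the threshold with a higher group mean of at least 5 FPKM and no overlap of the groups, up to 4 called members per list, GBSSI, SSIIIa, BEIIb, AGPL2, PPDKB, AMY3D, GLUA2, BIP1 and HSP101 whatever their values, the 12 largest lncRNAs of the authors' deposited table and the 5 largest lncRNA changes in each direction. Of the largest mRNA changes, only some in each direction are printed because they carry no names. Other members of the fixed lists are named where counts needed it, as are MSTRG.11401 and the neighbouring genes of chromosome 6, chosen after their values were seen.

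The scripts were tested on simulated data with known changes. Of simulated mRNA changes among 17050 genes, 25.4% were recovered at a log2 change of 0.5, 58.2% at 1 and 83.3% at 2, and 6.72% of the calls were false. Of simulated lncRNA changes among 455 rows, 0% were recovered at 0.5, 29.4% at 1 and 75.0% at 2, and 10.5% of the calls were false. Each size had 66 or 67 mRNA and 16 or 17 lncRNA changes, and the false calls were 8 of 119 and 2 of 19. Changes were placed only in rows above about 2 FPKM, so recovery in lower rows, which include most tested lncRNAs, is unknown. The simulated share of changed rows was also far smaller than the share called in the data. Alternatives covered the pseudocount, the minimum mean, quantile normalization, trimmed-mean scaling, rescaling without the 100 most abundant genes, a constant prior variance, a replicate block, a 2-fold minimum, joint adjustment of lncRNAs with mRNA genes, leaving out each sample in turn, and leaving out genes that switch on and off within a group. Pairs were compared with 10000 random re-pairings. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.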

Results

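RNA abundance was measured in rice endosperm, the starch-filled tissue of the grain, of the Japonica cultivar NingJing1 at 10 days after pollination. Plants had been moved at booting into growth chambers held at 36 °C by day and 33 °C by night (high temperature, n = 3 samples) or at 28 °C and 25 °C (normal temperature, n = 3 samples). The series addressed the part of long non-coding RNAs (lncRNAs) in the chalky grain that heat induces. The table listed 29907 mRNA gene rows and 578 lncRNA rows as FPKM, which summed to between 365035 and 380742 per sample. Sequencing depth is unknown, because the values are not read counts. Correlations of log2 values across genes, which are not independent replicates, lay between 0.913 and 0.928 within a group and between 0.865 and 0.872 across groups. The 10 most abundant rows held 34.8% to 37.5% of all FPKM in the high temperature samples and 30.3% to 31.3% in the normal temperature samples. Nothing in the labels says that the 3 samples of a group came from separate plants, so p-values measure only the spread between these samples.

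The first comparison asked which mRNAs differ in abundance between the temperatures. In high temperature, mRNAs of starch synthesis fell, among them GBSSI, BEIIb and PPDKB, and those of the alpha-amylase AMY3E, the glutelins GLUB4, GLUB5, GLUD and GLUB1 and the small heat shock proteins HSP17.9A and HSP16.9B rose. Of 17050 mRNA genes tested, 2222 were higher and 3887 were lower in high temperature at an adjusted p under 0.05 (limma, Benjamini-Hochberg). A change of at least 2-fold was seen in 513 of the higher and 399 of the lower genes. The 3 samples of one group lay on one side of all 3 of the other for 8814 genes, or 51.7%, where chance gives 10%. The share of called genes that rose was 36.4% on the deposited scale, 49.9% after trimmed-mean scaling and 47.2% after rescaling without the 100 most abundant genes. The median log2 fold change of the tested genes moved from -0.08 to 0.01 under trimmed-mean scaling.

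Genes outside the fixed lists carry no name in the sources used here, so only some identifiers are given in each direction. LOC_Os06g32020 rose from 0.14 ± 0.0265 to 67.6 ± 1.97 FPKM (SD, n = 3 per group), a log2 fold change of 5.91 (adjusted p = 3.4e-06). LOC_Os06g31890 rose from 0.297 ± 0.0924 to 56.2 ± 1.56 FPKM. These genes have neighbouring locus numbers, and reads could have been shared between near-identical copies. LOC_Os01g20780 had the largest fall by the naming rule, from 38.3 ± 3.07 to 0.247 ± 0.427 FPKM, a log2 fold change of -5.03. LOC_Os11g06720 fell from 51.3 ± 1.47 to 3.02 ± 0.224 FPKM, a log2 fold change of -3.70 (adjusted p = 9.8e-06). LOC_Os04g45520 was listed at 0 in each high temperature sample and at 20.53, 20.89 and 20.47 FPKM in the normal temperature samples.

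Starch synthesis genes fell together. Of 22 tested members, 18 fell, none rose and 4 did not pass the test, and the counts were the same adjusted over the list alone. The largest fall was in BT1 (LOC_Os02g10800), the carrier that brings ADP-glucose into the amyloplast, from 865 ± 17.8 to 196 ± 5.57 FPKM (SD, n = 3), a log2 fold change of -2.13 with a standard error of 0.03 (adjusted p = 9.8e-06). PPDKB (LOC_Os05g33570), a pyruvate orthophosphate dikinase, fell from 2142 ± 13.5 to 497 ± 21.4 FPKM, and the debranching enzyme isoamylase ISA1 (LOC_Os08g40930) from 447 ± 56.4 to 110 ± 18 FPKM. FLO2 (LOC_Os04g55230) had a log2 fold change of -1.93.

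The amylose-making granule-bound starch synthase GBSSI (LOC_Os06g04200) fell from 1380 ± 54.1 to 493 ± 44.3 FPKM (log2 fold change -1.49). The branching enzymes BEIIb (LOC_Os02g32660) and BEI (LOC_Os06g51084) fell by 1.93 and 1.31 on the log2 scale. Among subunits of ADP-glucose pyrophosphorylase, the enzyme that makes the glucosyl donor, AGPS2 (LOC_Os08g25734) fell from 1438 ± 43.1 to 437 ± 7.60 FPKM and AGPL2 (LOC_Os01g44220) from 756 ± 11.1 to 299 ± 6.39 FPKM. The soluble starch synthase SSIIIa (LOC_Os08g09230) had a smaller fall, from 108 ± 2.90 to 60.3 ± 1.78 FPKM. AGPL1, SSIVa, SSIIb and ISA2 did not pass, and AGPL1 (LOC_Os05g50380) had 43.0 ± 5.63 FPKM in high and 38.9 ± 4.77 FPKM in normal temperature. Each of the 18 genes that fell was lower in all 3 high temperature samples than in any normal temperature sample. The list mean was a log2 fold change of -1.12, and camera placed the list below the other genes with adjusted p = 7.8e-10, or adjusted p = 0.068 with an estimated correlation.

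**Figure D1:**
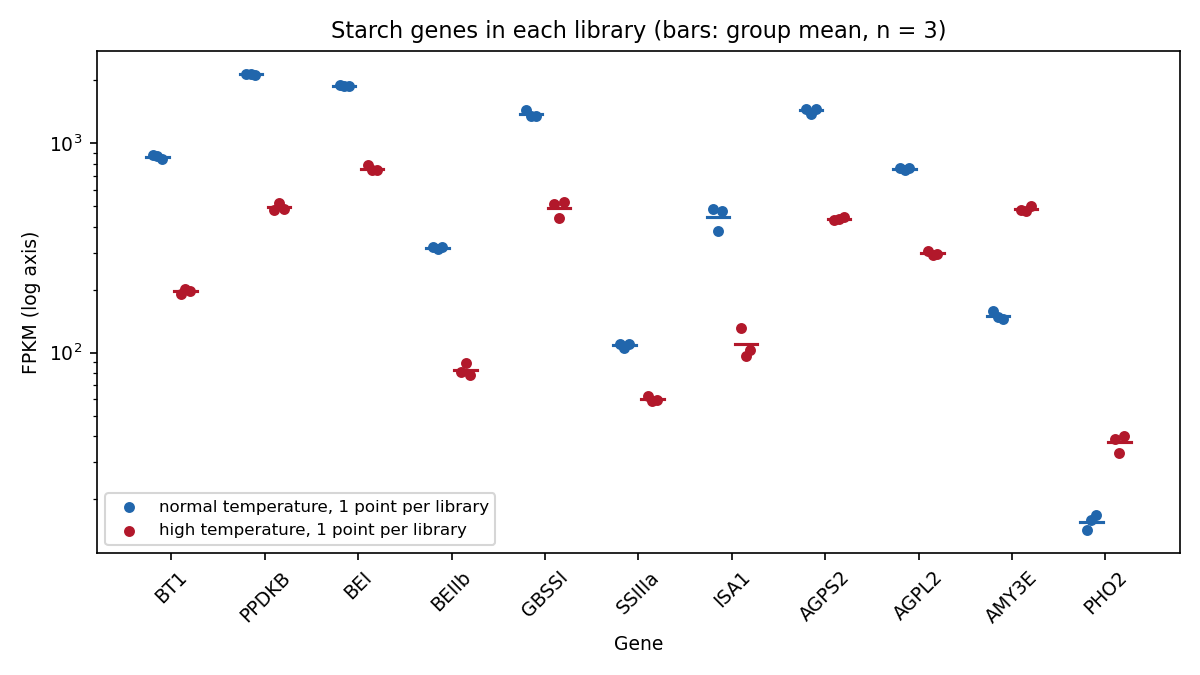
FPKM of 11 starch genes on a log axis, with 1 point per library, blue for normal and red for high temperature, and a bar at each group mean (n = 3). The 9 synthesis genes on the left lie lower in high temperature and AMY3E and PHO2 lie higher, AMY3E at 487 against 150 FPKM.

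Starch breakdown genes moved the other way where they changed. AMY3E (LOC_Os08g36900), an alpha-amylase, rose from 150 ± 7.36 to 487 ± 12.9 FPKM (SD, n = 3), a log2 fold change of 1.69 (adjusted p = 3.2e-05). The starch phosphorylase PHO2 (LOC_Os01g63270) rose from 15.6 ± 1.33 to 37.3 ± 3.73 FPKM, and the disproportionating enzyme DPE1 (LOC_Os07g43390) rose by 0.31 on the log2 scale. Of 6 tested members, 3 rose and none fell, with the same counts adjusted over the list alone. AMY3D (LOC_Os08g36910) lay under the minimum mean for testing, with 0.74, 0.92 and 0.99 FPKM in high and 0.01, 0 and 0 FPKM in normal temperature. Camera gave the list an adjusted p = 0.068, or adjusted p = 0.36 with an estimated correlation, and adjusted p = 0.034 after trimmed-mean scaling. DPE1 did not pass when any single sample other than normal temperature sample 1 was left out, with adjusted p between 0.056 and 0.10.

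Genes of sucrose import and cleavage were mostly lower. The cell wall invertase CIN2 (LOC_Os04g33740), which cleaves sucrose arriving in the grain, fell from 25.2 ± 0.671 to 3.24 ± 0.176 FPKM, a log2 fold change of -2.63 (adjusted p = 1.5e-05). The sucrose synthases SUS3 (LOC_Os07g42490) and SUS2 (LOC_Os06g09450) fell from 547 ± 18 to 154 ± 2.78 FPKM and from 206 ± 7.21 to 96.0 ± 1.90 FPKM. The sugar transporter SWEET4 (LOC_Os02g19820) rose from 11 ± 2.93 to 23.0 ± 0.929 FPKM. Of 9 tested members, 1 rose, 5 fell and 3 did not pass, over all genes and adjusted over the list alone. Camera gave adjusted p = 0.038, a call that was lost with an estimated correlation (adjusted p = 0.21) and under the settings given in the closing section.

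Seed storage protein genes rose in part. The glutelins GLUB4 (LOC_Os02g16830) and GLUB5 (LOC_Os02g16820) rose from 5499 ± 81.3 to 11578 ± 60.8 FPKM and from 10126 ± 88.2 to 21053 ± 287 FPKM (SD, n = 3), with log2 fold changes of 1.07 and 1.06 (adjusted p = 1e-05 for each). GLUD (LOC_Os02g15090) and GLUB1 (LOC_Os02g15169) had log2 fold changes of 0.97 and 0.86. GLUA2 (LOC_Os10g26060) rose by 0.11 on the log2 scale on the deposited values and had a log2 fold change of -0.04, with adjusted p = 0.52, after quantile normalization. Glutelins have near-identical copies, between which reads could have been split. Glutelins held 27.5% to 30.5% of all FPKM in the high and 20.8% to 22.6% in the normal temperature samples.

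Of 12 storage protein genes tested, 6 rose, 1 fell and 5 did not pass, against 7 and 2 adjusted over the list alone. The prolamin gene PROL16b (LOC_Os06g31060) was the one that fell, from 6.80 ± 0.575 to 5.40 ± 0.332 FPKM, a log2 fold change of -0.28. The far more abundant prolamin genes PROL16 (LOC_Os06g31070) and PROL13c (LOC_Os07g10580) did not pass. PROL16 had 6550, 7309 and 6417 FPKM in high and 95.0, 4443 and 4213 FPKM in normal temperature. PROL13c had a log2 fold change of -0.19 (adjusted p = 0.052). The globulin GLB1 (LOC_Os05g41970) was listed at 0 in the 3 high temperature samples and in normal temperature sample 2, and at 10536 and 10277 FPKM in the other two. That gene gave the list a mean log2 fold change of -0.19, while its median was 0.35. Camera placed the list above the other genes with adjusted p = 0.0013, which became adjusted p = 0.21 with an estimated correlation and adjusted p = 0.41 after quantile normalization.

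Genes of protein folding in the endoplasmic reticulum changed in both directions. The chaperone BIP1 (LOC_Os02g02410) rose from 283 ± 10.1 to 470 ± 108 FPKM, a log2 fold change of 0.71 (adjusted p = 0.022). PDIL2-3 (LOC_Os09g27830), a protein disulfide isomerase, rose by 0.44 and calreticulin CRT (LOC_Os07g14270) by 0.30 on the log2 scale. PDIL1-1 (LOC_Os11g09280) fell by 0.28 on the deposited scale and had a log2 fold change of 0.01 after quantile normalization. Of 10 tested members, 4 rose, 2 fell and 4 did not pass, with 5 and 2 adjusted over the list alone, and camera gave adjusted p = 0.10. BIP1 did not pass when any normal temperature sample was left out, with adjusted p between 0.057 and 0.068.

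In the heat shock list, 3 small heat shock protein genes rose and all other members fell or did not pass. HSP26.7 (LOC_Os03g14180), whose product is located in the chloroplast, rose from 4.11 ± 0.383 to 33.0 ± 1.14 FPKM, a log2 fold change of 2.74 (adjusted p = 2.7e-05). HSP17.9A (LOC_Os03g15960) rose from 57.7 ± 6.97 to 295 ± 6.82 FPKM and HSP16.9B (LOC_Os01g04380) from 35.0 ± 1.11 to 107 ± 3.58 FPKM. The heat shock factors HSFB2B (LOC_Os08g43334) and HSFA2C (LOC_Os10g28340) fell by 1.24 and 1.04 on the log2 scale, and the chaperone HSP70d (LOC_Os01g62290) fell by 0.63. HSP101 (LOC_Os05g44340), a chaperone that takes apart protein aggregates, had 20.7 ± 5.92 FPKM in high and 12 ± 3.05 FPKM in normal temperature (adjusted p = 0.085). Of 17 tested members, 3 rose, 3 fell and 11 did not pass, against 3 and 4 adjusted over the list alone. Camera gave the list adjusted p = 0.17. HSFB2B did not pass without normal temperature sample 2 or 3 (adjusted p = 0.058 and 0.057).

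Regulators of endosperm genes showed small changes. The transcription factors RPBF (LOC_Os02g15350) and NAC26 (LOC_Os01g29840) fell from 149 ± 7.42 to 91.4 ± 1.60 FPKM and from 742 ± 21.2 to 502 ± 8.86 FPKM, and RSR1 (LOC_Os05g03040) rose by 0.27 on the log2 scale. The other 3 of 6 tested members did not pass, the counts adjusted over the list alone were the same, and camera gave adjusted p = 0.62. RSR1 did not pass when any single sample other than normal temperature sample 2 was left out, with adjusted p between 0.051 and 0.082.

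Antioxidant enzyme genes split by isoform. The catalase CATB (LOC_Os06g51150) rose from 44.2 ± 2.34 to 85.6 ± 1.81 FPKM and the superoxide dismutase SODCC2 (LOC_Os07g46990) from 64.0 ± 14.6 to 125 ± 20.2 FPKM. The catalase CATA (LOC_Os02g02400) fell from 12.2 ± 0.0557 to 5.54 ± 0.524 FPKM and the ascorbate peroxidase APX2 (LOC_Os07g49400) from 46.0 ± 3.85 to 22.9 ± 3.71 FPKM. Of 8 tested members, 3 rose, 3 fell and 2 did not pass, also adjusted over the list alone, and camera gave adjusted p = 0.57. SODCC2 did not pass without high temperature sample 1 or 2 or normal temperature sample 1 or 3, with adjusted p between 0.052 and 0.053.

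Markers of other grain tissues were measured beside these groups. The green pericarp marker CAB2R (LOC_Os01g41710), a light-harvesting protein, fell from 74.1 ± 3.65 to 35.9 ± 2.78 FPKM, and the other 6 photosynthesis genes did not pass (camera adjusted p = 0.52). Of 5 tested embryo and aleurone markers, RAB16A (LOC_Os11g26790), a dehydrin, rose from 27.1 ± 1.26 to 150 ± 10.8 FPKM, a log2 fold change of 2.42, and VP1 (LOC_Os01g68370) rose by 0.15 on the log2 scale, a call that was lost without any 1 of the 6 samples (adjusted p between 0.067 and 0.095). The oleosin OLE16b (LOC_Os04g46200) had 649, 656 and 679 FPKM in high and 112, 569 and 74.3 FPKM in normal temperature and did not pass. Counts adjusted over the list alone were the same for both lists. Camera gave the embryo and aleurone list adjusted p = 0.038, a call that was lost with an estimated correlation (adjusted p = 0.21). The rise of RAB16A and the fall of CAB2R lay in the same samples as the fall of starch synthesis genes and the rise of glutelins.

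**Figure D2:**
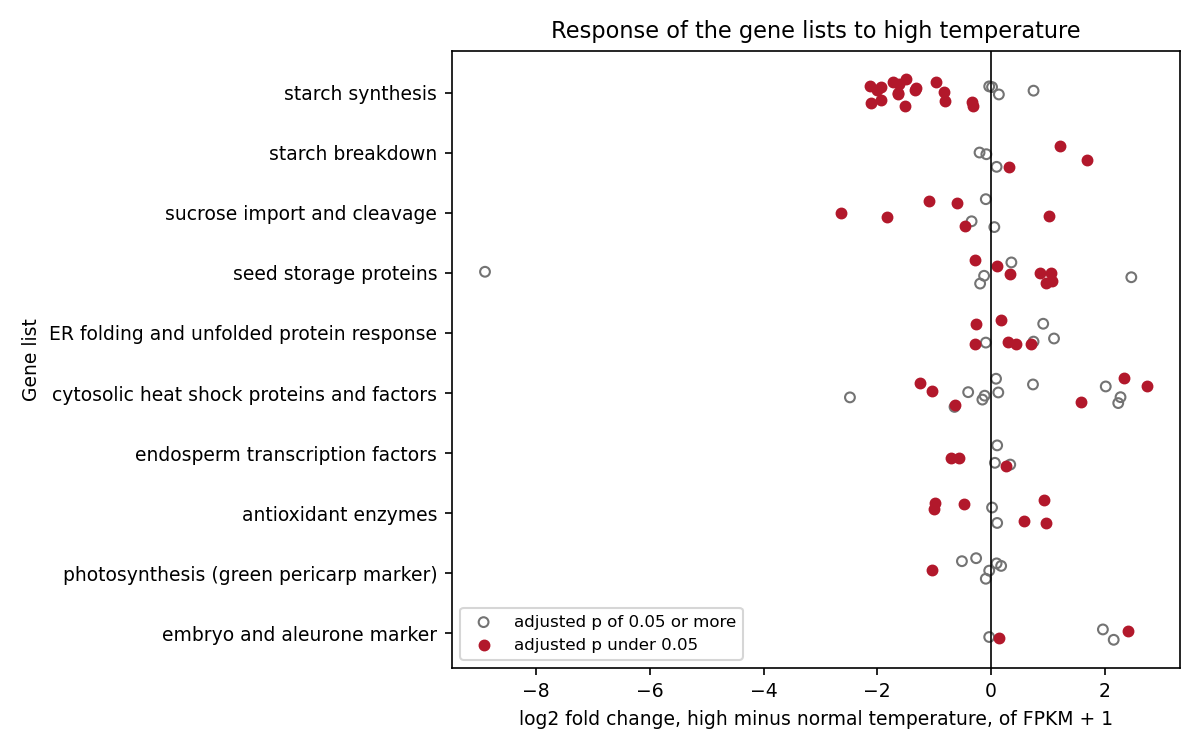
Log2 fold change (high minus normal temperature, of FPKM + 1) of each tested gene, 1 row of points per gene list, filled red where the adjusted p was under 0.05 and open otherwise, with random vertical placement. Starch synthesis shows 18 filled points, all below 0, and the open point at -8.90 is GLB1.

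The second comparison asked which lncRNAs differ between the temperatures. The largest fall was in MSTRG.4922, an intergenic lncRNA on chromosome 11 from 17082788 to 17083193, from 429 ± 8.16 to 10.5 ± 0.734 FPKM (SD, n = 3), a log2 fold change of -5.23 (adjusted p = 2.7e-05). MSTRG.11131 (chromosome 3, 25780471 to 25780696) fell from 54.7 ± 15.8 to 0.710 ± 0.246 FPKM, and MSTRG.10849 (chromosome 3, 18753084 to 18753598) from 41.4 ± 1.3 to 0.903 ± 0.271 FPKM. MSTRG.13824 on chromosome 4 and MSTRG.4736 on chromosome 11 had log2 fold changes of -3.97 and -3.38. The genome build of these positions is not given in the sources used here.

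The largest log2 rises among lncRNAs were in rows with low levels in normal temperature. MSTRG.4961 (chromosome 11, 18421424 to 18421736) was listed at 0 in each normal temperature sample and at 5.69, 4.66 and 5.49 FPKM in high temperature. MSTRG.12452 (chromosome 4, 11204012 to 11204954) rose from 0.020 ± 0.0173 to 4.75 ± 0.564 FPKM, a log2 fold change of 2.49. MSTRG.21717 on chromosome 9 rose from 0.0933 ± 0.0252 to 3.01 ± 0.198 FPKM and MSTRG.3631 on chromosome 10 from 0.190 ± 0.0954 to 2.91 ± 0.700 FPKM. Row 1 of MSTRG.7463 on chromosome 2 rose from 0.207 ± 0.0611 to 3.38 ± 1.21 FPKM, while row 2 of that locus did not pass. The most abundant lncRNA, MSTRG.11401, fell from 13782 ± 2381 to 6107 ± 938 FPKM, a log2 fold change of -1.17; it was chosen after its values were seen.

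Of 455 lncRNA rows tested, 53 were higher and 71 lower in high temperature (limma, adjusted p under 0.05), and 23 and 40 of these changed at least 2-fold. Samples of the groups did not overlap for 206 rows, or 45.3%, where chance gives 10%. The share of calls that rose was 42.7% for lncRNAs and 36.4% for mRNA genes (Fisher's exact test, two-sided, p = 0.16). That order turned round after quantile normalization (38.5% and 43.6%, p = 0.25), trimmed-mean scaling (48.3% and 49.9%, p = 0.78) and rescaling without the 100 most abundant genes (46.7% and 47.2%, p = 0.93), by the same exact test. Among calls of at least 2-fold it was 36.5% for lncRNAs and 56.2% for mRNA genes (Fisher's exact test, p = 0.0025). No other setting gave p under 0.05 by that test, and this p-value is not adjusted over the settings. It was computed on the deposited scale only and counts rows of 1 locus apart. A 2-fold minimum on log2(FPKM + 1) also leaves out more of the low rows. Tested lncRNAs had a median of the mean FPKM of 1.07, against 3.49 for tested mRNA genes.

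**Figure D3:**
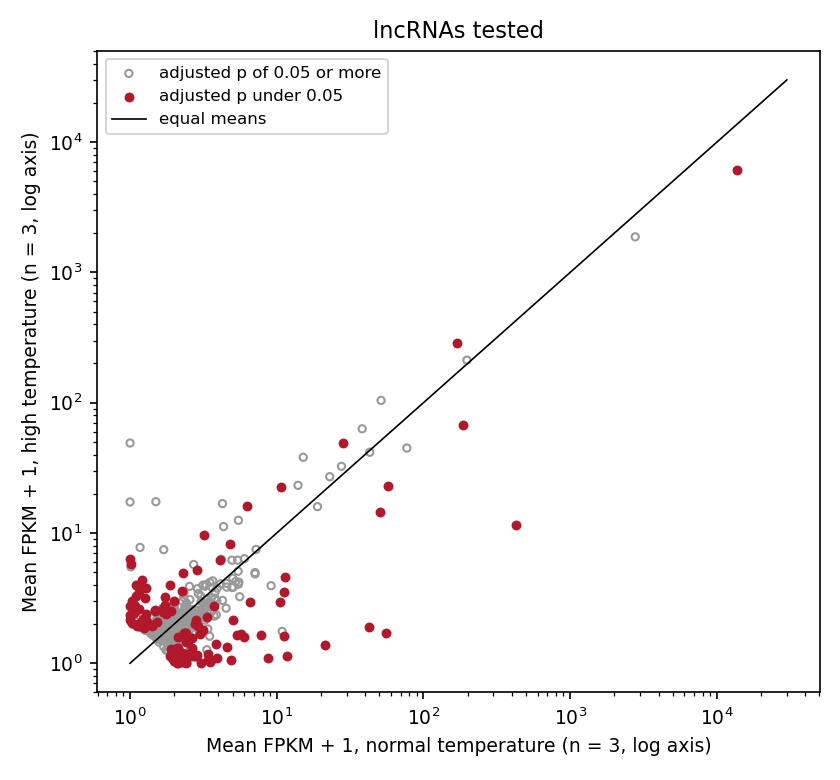
Mean FPKM + 1 of each tested lncRNA row in normal (horizontal) and high temperature (vertical), n = 3 per group, both on log axes, with red points for an adjusted p under 0.05 and a line at equal means. Most of the 455 rows lie near the lower end, and MSTRG.4922, at 429 against 10.5 FPKM, lies far below the line.

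By position relative to annotated genes, intergenic lncRNAs (class u) made up 294 of the rows tested, of which 37 rose and 54 fell. Antisense lncRNAs (class x) rose in 8 and fell in 8 of 96 rows, or 16.7%, against 31% for intergenic ones. Set against all other classes, intergenic and antisense rows gave adjusted p = 0.063 and adjusted p = 0.058 (Fisher's exact test, two-sided, adjusted over 6 classes). Of 25 rows that share splice sites with a gene (class j), 7 rows of 5 loci rose and none fell, which is 28% of rows called (Fisher's exact test against the other classes, p = 1). The loci, named after their values were seen, were MSTRG.19733 with 3 of the rows, MSTRG.16564, MSTRG.21815, MSTRG.3324 and MSTRG.5602, of which another row had a log2 fold change of -1.52 (adjusted p = 0.091). Intronic lncRNAs (class i) rose in 1 and fell in 6 of 20 rows. Whether reads were assigned by strand is not given in the sources used here, so antisense and overlapping lncRNAs cannot be separated with certainty from the gene they overlap.

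The authors' deposited table of changed lncRNAs listed 59 rows from 57 loci, 14 up and 45 down. Of 49 rows of those loci that could be matched and were tested, 46 had the direction of the authors' deposited table and 37 passed the test here. Of the other rows that passed here, 80 were not in the authors' deposited table and 7 belonged to loci of that table whose rows could not be told apart. The calls in both had a median absolute log2 fold change of 1.59, and those found only here 0.85.

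The authors' deposited table of starch-metabolism genes paired 6 mRNAs with 36 lncRNA transcripts in 149 pairs. Among its 5 tested mRNAs, AGPS2, AGPS1 (LOC_Os09g12660), SSIIa (LOC_Os06g12450) and 1 gene without a name fell and AMY3E rose, also adjusted over the list alone. SSIIa, a starch synthase, fell from 135 ± 1.56 to 42.4 ± 1.16 FPKM and AGPS1 from 175 ± 9.22 to 56.7 ± 2.73 FPKM. Camera placed the list lower with adjusted p = 0.041, or adjusted p = 0.21 with an estimated correlation; the study chose this list on these samples, so it is no independent evidence of the direction.

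Pairs of mRNA and lncRNA carried 79 positive and 70 negative Pearson correlations in the authors' deposited table, none smaller in size than 0.951. SSIIa had 22 positive and 9 negative pairs, and AMY3E 7 positive and 23 negative pairs. In 130 pairs whose lncRNA row was unambiguous, the sign of the authors' correlation was that of the product of the 2 log2 fold changes in 70 positive and 60 negative pairs. Of 102 pairs with both members tested, 59.8% changed in the same direction, against 60.1% after random re-pairing (permutation test, two-sided, p = 1). These pairs joined only 5 mRNAs with 28 lncRNAs, and most of the mRNAs were paired with most of the lncRNAs. Re-pairing could therefore hardly change the share, and the test cannot tell whether the pairing carries information on direction.

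Pairings of microRNAs with lncRNAs numbered 9030 in the authors' deposited table, between 745 microRNAs and 517 lncRNA loci. A pairing was listed for 97.5% of lncRNA loci that changed and 97.4% of the other tested loci (Fisher's exact test, two-sided, p = 1). As nearly every locus had a pairing, that test could show little. The median number of paired microRNAs was 8 for changed and 10 for other tested loci, a difference that was not tested. MicroRNA levels were not analysed here.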

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

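Leaving out genes that switch on and off within a group, and comparing the share of rises between lncRNAs and mRNA genes across settings, were chosen after the data were seen; the other alternatives were fixed before. Counts of changed genes moved by over 1.5 times under 2 alternatives, by their own construction. A mean of at least 2 FPKM left 1433 mRNA genes higher, and 11 lncRNAs higher and 23 lower. A minimum change of 2-fold left 513 and 399 mRNA genes and 23 and 40 lncRNAs. Over the other settings, mRNA genes numbered up to 2872 higher and 4034 lower. Without 1 sample at a time, 1815 to 1905 mRNA genes were higher and 3151 to 3297 lower, 38 to 47 lncRNAs were higher and 56 to 75 lower, and between 4692 and 4861 of the 6109 mRNA calls were kept with 0 changes of sign.

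Starch synthesis stayed past the threshold under every alternative run except camera with an estimated correlation (adjusted p = 0.0682). With that correlation, the calls were also lost for sucrose import and cleavage (0.213), seed storage proteins (0.206), embryo and aleurone markers (0.206) and the authors' starch-metabolism table (0.206). Adjusted p was 0.0677 for the sucrose list and for the authors' table at a mean of at least 2, 0.117 for the authors' table without a filter on the mean, and 0.00809 for starch breakdown without that filter. Quantile normalization gave adjusted p = 0.042 for starch breakdown, 0.0526 for the sucrose list, 0.411 for storage proteins and 0.0308 for folding in the endoplasmic reticulum. Starch breakdown passed after trimmed-mean scaling (adjusted p = 0.0339) and rescaling without the 100 highest genes (0.037). A constant prior variance gave adjusted p = 0.050 for the sucrose list and the embryo and aleurone markers and 0.0585 for the authors' table. Without on-off genes, adjusted p was 0.0503 for the sucrose list and 0.0538 for the authors' table, and the embryo and aleurone list had too few members there and at a mean of at least 2. With 1 sample left out, adjusted p ranged from 0.0455 to 0.103 for starch breakdown, 0.0368 to 0.0924 for the sucrose list, 0.044 to 0.253 for folding in the endoplasmic reticulum, 0.016 to 0.0593 for the embryo and aleurone markers and 0.044 to 0.0631 for the authors' table. The sucrose list and the authors' table did not pass without high temperature sample 1 or normal temperature sample 2, nor did the embryo and aleurone markers without high temperature sample 1. Starch breakdown passed without high temperature sample 2 or normal temperature sample 1, and folding in the endoplasmic reticulum without normal temperature sample 3. The cause was not tested.

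Of the named genes, GLUA2 and PDIL1-1 reversed under quantile normalization, to log2 fold changes of -0.04 and 0.01. Other genes named by the fixed rule kept their direction, and 33 of their values under an alternative no longer passed. Genes named outside that rule, such as PROL16b, BEI, HSFA2C, HSP70d and MSTRG.11401, were not followed one by one across the settings. The share of calls that rose, lncRNA minus mRNA, was 6.37 percentage points and reversed to -5.11 under quantile normalization, -1.56 under trimmed-mean scaling, -0.561 when rescaled without the 100 highest genes and -19.7 among changes of at least 2-fold. Replicate numbers did not pair the samples: residual correlations of same-numbered samples were -0.017, -0.0028 and 0.0039. With the replicate block, 1657 mRNA genes were higher and 2910 lower, 49 lncRNAs were higher and 65 lower, and the sucrose list and the authors' table had adjusted p = 0.0566 each. Count-based alternatives were not run, as the values are not counts. Unknown depth limits what can be said of low values.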

Other observations

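The tests of composition and of endosperm share for the starch genes, of a temperature effect on switching genes and of the placement of strong risers were chosen after the results were seen.

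A group of genes with neighbouring locus numbers on chromosome 6 rose from near 0. Of 30 mRNA genes that rose at least 8-fold on the log2(FPKM + 1) scale, 7 lay within 10 consecutive tested genes, among them LOC_Os06g31890 and LOC_Os06g32020, with high temperature means of 13.1 to 67.6 FPKM and normal temperature means of at most 0.297 FPKM. No more than 3 fell in such a window in 1000 random placements (permutation p = 0.001, the smallest they can give), which argues against chance placement along the chromosomes. A hypothesis is that these genes respond as a cluster, but reads shared between near-identical copies may also give several of them similar values, and this was not tested.

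The fall of starch synthesis genes was weighed against a few abundant genes taking more of the reads, since glutelins took a larger share of FPKM in high temperature. The list mean was -1.12 as deposited, -1.03 after rescaling without the 100 highest genes and -1.01 after trimmed-mean scaling. These means argue against composition as the whole cause. The standard error of the rescaled mean, 0.17, was taken over the 22 genes, so it measures spread between genes and not between samples. A smaller share of starchy endosperm would by itself lower glutelins too, yet 6 of 7 tested glutelins rose and 0 fell. After rescaling, trimmed-mean scaling and quantile normalization, 6, 6 and 4 rose. GLUC was left out of these counts, as the reference gives its symbol to another gene. GLUB1 and GLUD, which rose, were not checked by the reference either, but GLUB4 and GLUB5 were checked and also rose. Outside the glutelins, PROL16b was the only storage protein gene that passed, with a log2 fold change of -0.28. Of 6 tested endosperm transcription factors, 2 fell (RPBF and NAC26, log2 fold changes of -0.70 and -0.56), 1 rose and 3 did not pass. The glutelins were picked after their rise was seen, and a rise of their own could hide a smaller endosperm share. These values therefore cannot decide whether the endosperm share was smaller. Of the markers of other tissues, RAB16A rose from 27.1 to 150 FPKM, VP1 rose by 0.15 on the log2 scale and CAB2R fell, while 3 of 5 embryo and aleurone and 6 of 7 photosynthesis markers did not pass, so more RNA from embryo or aleurone, whose list had adjusted p = 0.038 (0.206 with an estimated correlation), stays open. A response to temperature and a faster progress of grain filling at high temperature could both give the pattern. The design has 1 age and does not separate them, and neither was tested. As the temperatures were held in growth chambers, any other difference between the chambers cannot be told apart from temperature.

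Some FPKM values switched on and off among the samples of a group. In 707 mRNA genes the highest sample of a group was at least 5 FPKM and at least 8 times the lowest, as for HSP16.9A (LOC_Os01g04370) at 400, 9.01 and 418 FPKM in high and 120, 0 and 121 FPKM in normal temperature. A single poor library is argued against, as no library held more than 19.8% of the 1251 low values. Switching was not confined to high temperature, as 482 genes switched in high and 418 in normal temperature, a ratio of 1.15. Its upper bound of 1.32 at 2 standard errors treats genes as independent, although all come from the same 3 samples per group. Whether temperature changes the number of switching genes therefore cannot be told. Reads moved between neighbouring gene models cannot be told apart from chance: over the 750 cases of a gene switching in a group that had a tested neighbour, a neighbour moved the opposite way in 21.3% and a random gene in 21.1%, a ratio of 1.01, but random draws ranged from 18% to 24.7%. The cause may lie in how transcripts were assigned, which was not tested.

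High correlations between starch mRNAs and lncRNAs were set against the difference between the temperature groups. Of 57456 pairs of an mRNA and an lncRNA called with at least a 2-fold change, 42.8% reached the smallest absolute correlation of the authors' deposited table, 0.951. After removing group means, the sign of the correlation was that of the table in 62.3% of 130 pairs, although pairs picked for a high correlation lean that way. Neither value reached a bound set beforehand, so a link within the groups and the group difference alone cannot be told apart with 3 samples per group.

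Other splits of the 6 samples gave few calls. In 10 splits into 3 and 3, the real one gave 2222 higher and 3887 lower mRNA genes and at most 12 were called in one direction by another split; the values for lncRNAs were 53 and 71 against at most 1. The real split put 5 gene lists past the threshold and another split at most 2. For each of these results, 1 split, the real one, gave a value as large, and 10 splits are too few for a share under 0.05. Every other split also mixes both temperatures in each group, so a difference between the temperatures widens the spread within its groups. The few calls of the other splits are therefore no further support for the real one.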
